A study of Populus trichocarpa and Populus tremula x Populus alba with 22 samples.

How the data were processed

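The data were 22 RNA-seq libraries of poplar in 2 experiments. In the first, Populus trichocarpa plants grew hydroponically for 21 days with 0 µM or 10 µM Fe, and the young leaf and the 3rd internode of 6 plants were sampled, giving 3 libraries per tissue and Fe level. In the second, leaf and stem of 4-month-old Populus tremula x Populus alba plants carrying a PtrbHLH011 overexpression construct or an empty vector were sampled, with 3 libraries per genotype in leaf and 2 in stem. PtrbHLH011 is a basic helix-loop-helix transcription factor. Reads were paired-end, 150 bp. Per the labels' protocols, the Fe libraries were Illumina libraries with poly(A) selection and the overexpression libraries were DNBSEQ strand-specific mRNA libraries, with a different RNA kit, so the experiments were never fitted together. Groups, replicate numbers and plant codes were taken from the labels. The library names of the overexpression plants share a single stem, and the number of independent transgenic lines is not given in the sources used here. Where nothing states that libraries came from separate plants, p-values measure only the spread between these libraries.

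The deposited values are a signal per gene, gene counts divided by a size factor for each library, in 4 tables with 42950 genes each, 1 table per comparison. HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 2.11.40.7 are named in the submitters' processing notes, without their roles. The column headers name StringTie gene counts for young leaf only. The genome build and annotation are not given in the sources used here beyond the form of the gene IDs. How the authors' counting treated strand, overlapping genes and near-identical gene copies is likewise not given, so values of such genes are uncertain. Every value was a whole multiple of a step per library, and dividing by that step returned whole numbers for 100% of values within a tolerance of 0.001. They are called reads here, but they may be estimates rounded to whole numbers and not sequenced reads. Depths, floors, the comparison with sampling noise and the count tests rest on that reading. The recovered totals ranged from 26620695 to 68689878 reads per library. Floors from 0 reads cover counting error only.

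The test fixed before the data were examined was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(deposited value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were tested if they had a value of at least 10 in at least as many libraries as the smaller group held. Fold changes named as log2 are on the log2(value + 1) scale, which understates the change of low genes. Where a group had 0 reads in all its libraries, the fold is a lower bound against 3 reads per library. The tissue difference of the Fe response was tested on the leaf minus internode difference within each plant. The overexpression effect was compared between leaf and stem by fitting the libraries of both tissues together in limma. That fit did not pair plants and took a common variance per gene for both tissues. Overlaps of calls were tested with Fisher's exact test over the genes tested in both comparisons, and genes are not independent replicates. Count tests on the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, were alternatives, as were pseudocounts of 0.1 and 5, no filter and a filter at 50, quantile normalization, upper-quartile scaling, sample weights, a 2-fold minimum, a replicate block and leaving out each library. On the recovered reads edgeR called 1895 genes in young leaf, 97 in internode, 5847 in overexpression leaf and 9237 in overexpression stem.

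The files do not pair gene IDs with names, and 0 IDs matched the reference table used here (assembly P.trichocarpa_v4.1). The 18 gene lists fixed beforehand, among them lignin, cellulose, Fe transport and photosynthesis genes and markers of other cell types, therefore had no members, and 0 of them were tested. The PtrbHLH011 gene itself was not identified among the IDs, so its level was not checked against the genotype labels. The rule for named genes gives in that case at most 2 IDs that rose and 2 that fell per comparison: those with the largest log2 fold change among called genes with a mean value of at least 50 and no overlap between the groups. In their place, leaf-enriched and stem-enriched genes were defined after the data were seen, as genes at least 8-fold apart between the tissues and at 20 or more CPM in the higher tissue. They were defined on the control libraries of the other experiment, empty-vector leaf and stem for the Fe comparisons and Fe-sufficient leaf and internode for the overexpression comparisons. The 2 definitions gave 1754 and 532 leaf-enriched genes, with 375 shared, and 978 and 561 stem-enriched genes, with 114 shared. The 2 stem-enriched sets are thus mostly different genes. They were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation, as a family of 8 tests. The comparison of overexpression effects between leaf and stem, the response groups, the thinning of reads and the choice of 4 genes for a plot were also made after the data were seen.

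The steps were tested on simulated counts drawn from the real means and library sizes. At 4-fold, limma recovered 79.0% of changed genes in young leaf (28699 genes), 73.0% in internode (29301 genes), 87.0% in overexpression leaf (26996 genes) and 82.8% in overexpression stem (24878 genes). At 2-fold the shares were 23.2%, 14.3%, 50.0% and 55.6% in the same order. False calls made up 3.77%, 2.25%, 6.21% and 6.16% of limma's calls, and 19.7%, 23.4%, 13.2% and 5.71% of those of DESeq2. In young leaf 99 of the tested genes were changed 2-fold and 100 were changed 4-fold, with similar numbers in the other comparisons. Shares of false calls depend on how many genes change, so they do not carry over to the real calls. For the tissue difference of the Fe response, 0% of simulated 2-fold or 4-fold differences were recovered (27391 genes). Libraries of a group differed by far more than sampling noise (chi-square per degree of freedom from 9.41 to 270), so none was counted as a duplicate. In the internode the deviations of libraries with the same replicate number correlated at 0.27, 0.12 and 0.48, all above 0.1. These numbers were therefore treated as pairing the libraries, from the data and not from the labels, which give them different plant codes. The internode libraries numbered 3, control plant P17 and Fe-deprived plant P7, were registered in the series apart from all others. Whether they were also prepared or sequenced apart is not given in the sources used here.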

Results

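Transcripts were profiled in 12 libraries of the Fe experiment and 10 of the overexpression experiment. Young leaf and 3rd internode of Fe-deprived and Fe-sufficient plants had 3 libraries each, at 29840597 to 68689878 reads. Leaf of overexpression and empty-vector plants had 3 libraries each and stem had 2 each, at 26620695 to 30101710 reads. Between 28318 and 33012 of 42950 genes had at least 1 read in a library. Genes are given by ID, since the files do not pair IDs with names. Values are normalized counts as mean ± SD.

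The first comparison asked which transcripts changed in young leaves after 21 days without Fe. Potri.005G096200 rose from 1.83 ± 1.61 to 39193 ± 19150 (n = 3 each, log2 fold change 13.87 ± 0.58 SE, limma adjusted p = 0.000185). Potri.006G037600 had 0 reads in the 3 control leaves and 8028 ± 6418 without Fe, at least 2361-fold higher (limma adjusted p = 0.000185). Potri.002G188000 fell from 800 ± 448 to 0.854 ± 0.917 (limma adjusted p = 0.00121). Potri.015G050200 fell from 1888 ± 2022 to 31.5 ± 53.0 (limma adjusted p = 0.0366), a call that edgeR did not make (adjusted p = 0.0588) and that 5 of the 6 fits without a library lost. Of 28632 genes tested, 870 rose and 937 fell, and 75 of the former and 86 of the latter changed at least 16-fold. The 10 most abundant genes held 9.45 ± 0.615% of reads in control leaves and 6.59 ± 0.403% in Fe-deprived leaves (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Of 855 stem-enriched genes tested, 17 rose and 45 fell, with a median log2 change of -0.14 (camera p = 0.0315, adjusted over 8 tests 0.0841, p = 0.464 with an estimated correlation). The 1807 calls became 282 without control replicate 2, 383 without control replicate 3, 233 and 230 without Fe-deprived replicates 2 and 3, and 3165 without Fe-deprived replicate 1. DESeq2 called 4744 genes and limma with sample weights 6530.

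**Figure D1:**
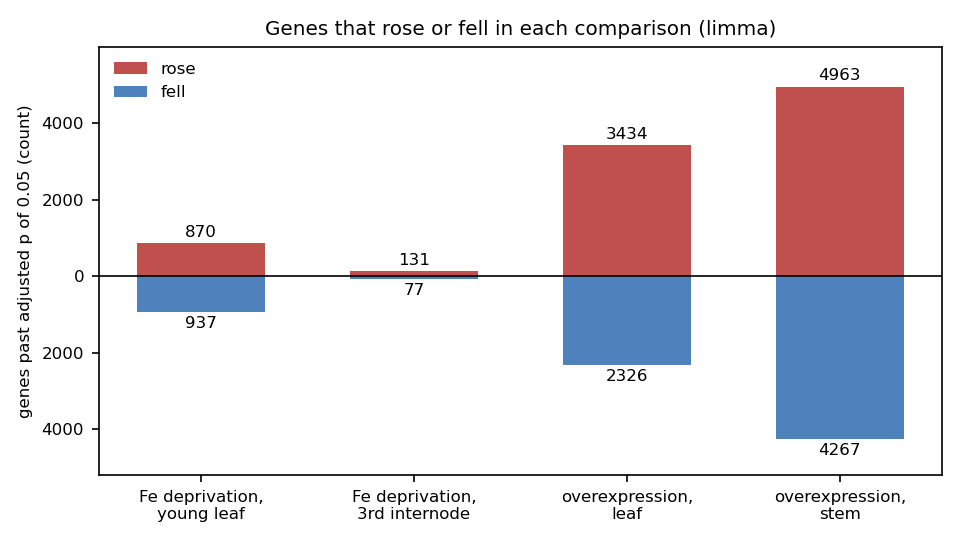
Bars give the number of genes that rose (above 0) or fell (below 0) at an adjusted p of 0.05 in limma, for each comparison on the horizontal axis. Fe deprivation gave 1807 calls in young leaf and 208 in the 3rd internode, and overexpression gave 5760 in leaf and 9230 in stem.

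The same question was put to the 3rd internode of the same plants. Potri.013G101000 rose from 8.96 ± 8.68 to 2665 ± 1804 (n = 3 each, limma adjusted p = 0.0389). Potri.002G055566 had 0 reads in the 3 control internodes and 398 ± 355 without Fe, at least 114-fold higher (limma adjusted p = 0.0251). Potri.007G045000 fell from 1756 ± 613 to 94.8 ± 47.1 (limma adjusted p = 0.0294) and Potri.019G093000 from 215 ± 109 to 9.85 ± 5.05 (limma adjusted p = 0.0397). Of 29219 genes tested, 131 rose and 77 fell. Among the 943 stem-enriched genes tested, 27 rose, 0 fell and 916 did not pass limma's test, and adjusted over the list alone 283 rose and 21 fell. Their median log2 change was 0.71, and the medians of the 3 Fe-deprived libraries, 0.60, 0.62 and 0.92, lay above those of the 3 controls, -0.11, -0.22 and 0.31 (camera p = 1.81e-18, p = 0.0827 with an estimated correlation). With a 4-fold class limit the median was 0.32. Of 1701 leaf-enriched genes, 7 rose and 8 fell (limma's camera, adjusted p = 0.228). With the replicate number as a block 401 genes were called, 235 rising and 166 falling. The 4 named genes each lost their call in 4 of the 6 fits without a library. Potri.002G055566 and Potri.019G093000 were not called by edgeR (adjusted p = 0.0678 and 0.0530), nor Potri.013G101000 by limma with a pseudocount of 0.1 (adjusted p = 0.0793). The 208 calls became 0 without control replicate 2 or any 1 Fe-deprived library, 1499 without control replicate 1 and 1090 without control replicate 3.

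Leaf and internode responses were compared within plants. Of 27351 genes tested in both tissues, 36 were called in both, and 32 of these changed in the same direction, 21 rising and 11 falling (Fisher's exact test of direction, p = 8.67e-06). Both tissues came from the same 6 plants by their labels. Deviations of the leaf and internode libraries of a plant correlated at 0.33 for P11 and at 0.0039 to 0.12 for the other plants. Each of those others correlated more highly with a different plant, so the pairing rests on the labels. Potri.002G055566 rose in leaf too, from 16 ± 19 to 7269 ± 1988 (n = 3 each, limma adjusted p = 0.00785), and its responses did not differ detectably (leaf minus internode log2 1.56 ± 1.28 SE, limma adjusted p = 0.588). The leaf minus internode difference was positive for Potri.005G096200 (log2 7.56, limma adjusted p = 0.0336) and negative for Potri.002G188000 (-7.63, limma adjusted p = 0.0242). Neither was called in the internode, where Potri.005G096200 went from 3.19 ± 5.52 to 241 ± 236 (limma adjusted p = 0.0655). Potri.002G188000 went there from 26.7 ± 17.7 to 9.71 ± 4.39 (limma adjusted p = 0.475). From that control level it could not have fallen as far as in leaf, so the floor sets part of its difference. In total 135 genes differed, with the leaf response higher for 28 and lower for 107. Of the 107, 62 were called as falling in leaf and 86 had a positive internode log2 change. With the internode replicate number as a block 1 gene was called, Potri.002G188000 (limma adjusted p = 0.0372), and Potri.005G096200 was not (limma adjusted p = 0.0846). The count became 0 without plant P13 or P30, 7 without P7, 10 without P22 and 82 without P17.

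The overexpression comparisons asked which transcripts differed in plants labelled as overexpressing PtrbHLH011, whose own level was not checked here. In leaf, Potri.008G099900 rose from 6.58 ± 0.992 to 19302 ± 2672 (n = 3 each, limma adjusted p = 1.32e-07). Potri.018G098200 rose from 20.7 ± 35.8 to 5641 ± 1697 (limma adjusted p = 0.00293). Potri.012G130600 fell from 2319 ± 137 to 23.2 ± 14.6 (limma adjusted p = 0.000155). Potri.001G139700 fell from 125 ± 60.4 to 0 reads in the 3 overexpression leaves, at least 43.8-fold lower (limma adjusted p = 0.000326). Of 27024 genes tested, 3434 rose and 2326 fell, and 385 rose against 27 that fell by at least 16-fold. With quantile normalization 2977 rose and 2842 fell. Of 517 leaf-enriched genes tested, 205 fell and 38 rose, and adjusted over the list alone 257 fell and 39 rose. Their median log2 change was -0.53 (camera p = 8.72e-15, p = 0.0714 with an estimated correlation), and -0.30 with quantile normalization. Of 430 stem-enriched genes, 85 rose and 30 fell (limma's camera, adjusted p = 0.134). The 10 most abundant genes held 7.48 ± 0.476% of reads in empty-vector and 4.57 ± 0.726% in overexpression leaves (exact permutation test, two-sided, p = 0.1, the smallest possible). The 5760 calls became 3442 without empty-vector replicate 2, 2739 without overexpression replicate 3, 3151 with a 2-fold minimum and 12199 with sample weights.

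**Figure D2:**
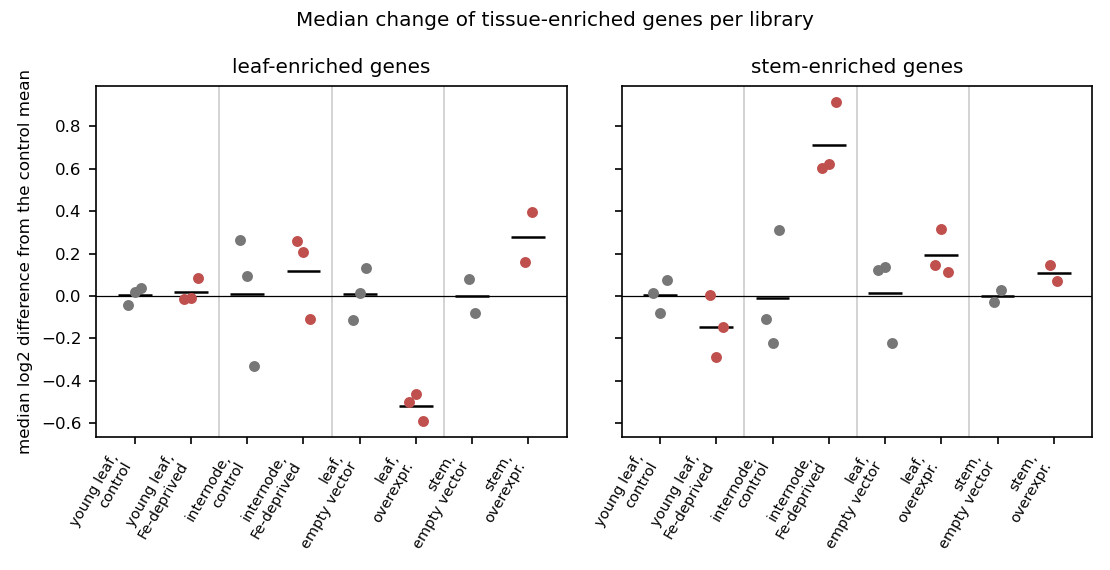
Each point is the median, over leaf-enriched (left) or stem-enriched (right) genes, of a library's log2 difference from the mean of its control group, with bars at the group mean. Stem-enriched genes lay between 0.60 and 0.92 in Fe-deprived internodes, and leaf-enriched genes between -0.59 and -0.46 in overexpression leaves. The gene sets of a class differ between the Fe and the overexpression libraries.

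In stem, Potri.005G113400 rose from 190 ± 27.2 to 53042 ± 2495 (n = 2 each, limma adjusted p = 4.99e-05), 279-fold. Its rise in leaf was 278-fold, from 330 ± 54.3 to 91888 ± 18168 (n = 3 each, limma adjusted p = 1.74e-06). Potri.T155100 had 0 reads in both empty-vector stems and 721 ± 36.7 under overexpression, at least 236-fold higher (limma adjusted p = 0.00113). Potri.003G022800 fell from 679 ± 568 to 1.98 ± 2.80 (limma adjusted p = 0.00339). Potri.019G073400 fell from 236 ± 201.1 to 0 reads in both overexpression stems, at least 80.4-fold lower (limma adjusted p = 0.00221). Of 24810 genes tested, 4963 rose and 4267 fell. Of 417 stem-enriched genes, 118 rose and 66 fell, and of 361 leaf-enriched genes 88 rose and 55 fell (limma's camera, adjusted p = 0.139 for each). The named genes, like the 9230 calls, were lost without either overexpression library, where the remaining library is assumed to vary like the empty-vector stems; 6061 calls were left without empty-vector replicate 1. A 2-fold minimum left 4125 genes.

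Effects of overexpression were set against each other across tissues. Of 1870 genes called in leaf and in stem, 604 changed in the same direction and 1266 in opposite directions (32.3% the same, Fisher's exact test, p = 3.32e-54). Genes that rose in leaf and fell in stem numbered 693, against 438 for independent lists, and 573 fell in leaf and rose in stem, against 424. Across the 23372 genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson r of -0.19 and a Spearman rho of -0.23. The rises of Potri.005G113400 did not differ detectably (leaf minus stem log2 -0.01, limma adjusted p = 0.974). Potri.008G099900 rose in both tissues and by more in leaf (leaf minus stem log2 8.73, limma adjusted p = 6.5e-06).

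**Figure D3:**
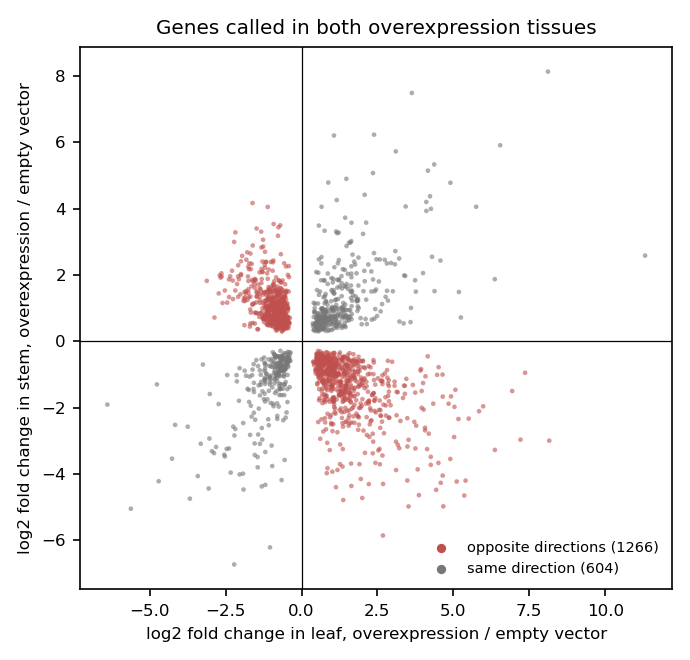
Each point is a gene called in both overexpression tissues, with its log2 fold change in leaf on the horizontal axis and in stem on the vertical axis. Red points, 1266 genes, changed in opposite directions and grey points, 604 genes, in the same direction.

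The last comparison asked whether Fe deprivation and overexpression moved the same genes. In leaf, 512 genes were called in both experiments, and 306 of them (59.8%) changed in the same direction (Fisher's exact test, p = 1.03e-06). Across all 25301 genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson r of 0.04 and a Spearman rho of -0.02. Genes that rose in both numbered 153, against 93.2 for independent lists, and 153 fell in both, against 73.1. A further 138 fell without Fe and rose under overexpression, against 99.1. Potri.005G096200 rose in overexpression leaves from 129 ± 96.3 to 15571 ± 1448 (n = 3 each, limma adjusted p = 0.000196), and Potri.002G055566 from 19.99 ± 10.3 to 3073 ± 935 (limma adjusted p = 0.000196). Potri.012G130600 also fell without Fe, from 10558 ± 853 to 168 ± 126 (n = 3 each, limma adjusted p = 0.00281). Potri.005G113400 went the other way, falling from 361 ± 94.7 to 10.2 ± 3.6 in Fe-deprived leaves (n = 3 each, limma adjusted p = 0.00271). In internode and stem, 79 genes were called in both and 25 (31.6%) changed in the same direction (Fisher's exact test, p = 0.0341). Across the 23622 genes tested in both, r was -0.11 and rho -0.09. Genes that rose in Fe-deprived internodes and fell in overexpression stems numbered 42, against 18.2 for independent lists (Fisher's exact test, p = 3.71e-08). Of those that fell in Fe-deprived internodes, 12 rose in overexpression stems, against 10.9 (Fisher's exact test, p = 0.734), and 13 fell, against 8.99 (Fisher's exact test, p = 0.144).

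**Figure D4:**
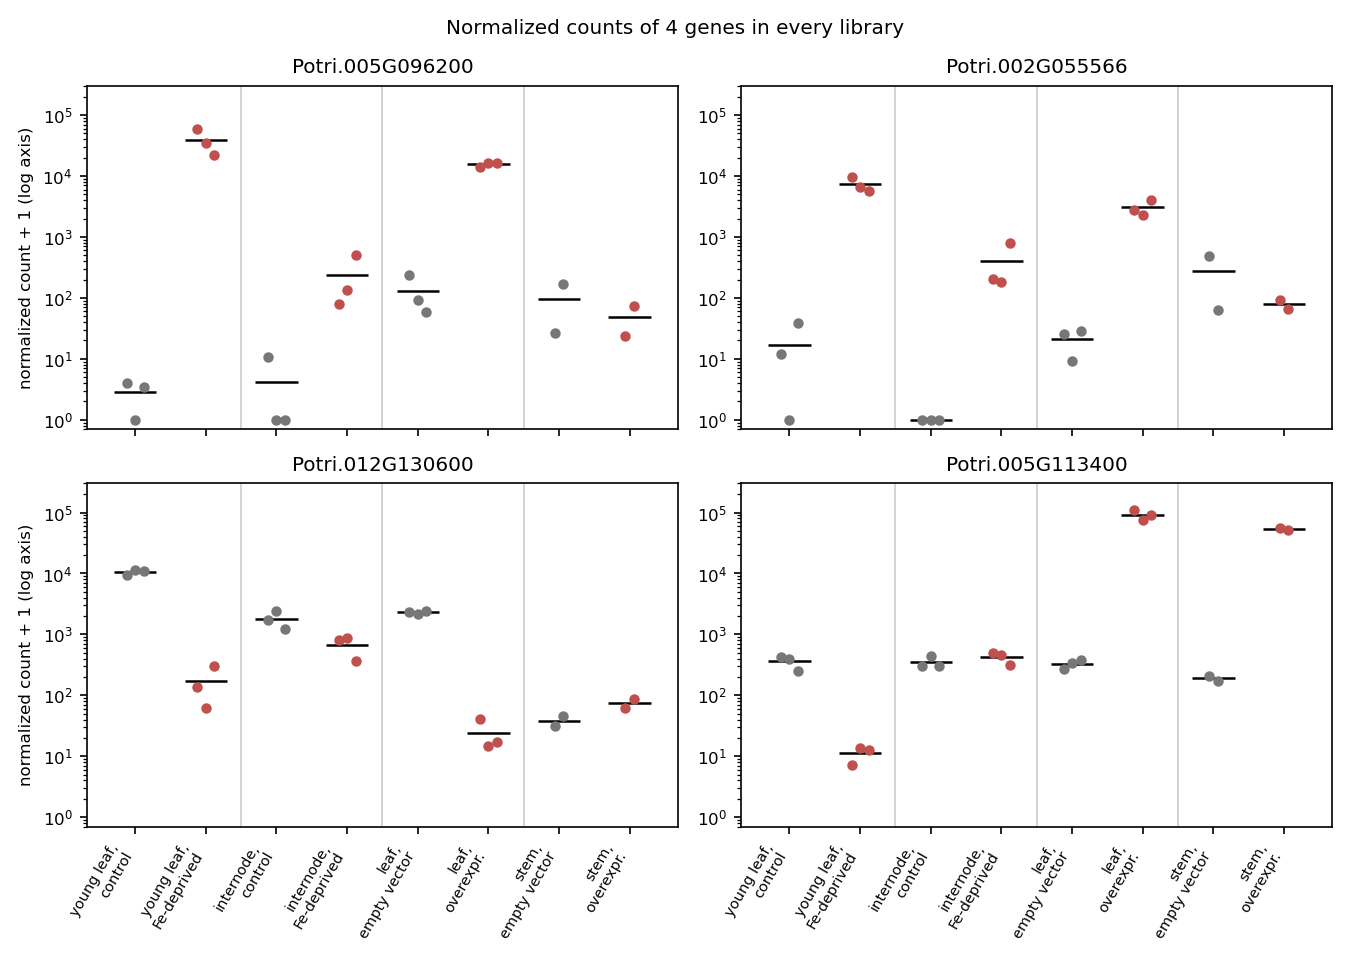
Points are libraries and bars group means of the normalized count plus 1, on a log axis, for 4 of the named genes, with controls in grey and Fe-deprived or overexpression libraries in red. Potri.005G096200 reached a mean of 39193 in Fe-deprived and 15571 in overexpression leaves.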

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

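Apart from the test of the Fe response between tissues and the splits, the tests here were chosen after the data were seen. The Fe response differed between leaf and internode, by a test of the difference, for 135 genes, among them Potri.005G096200 (leaf minus internode log2 7.56) and Potri.002G188000 (-7.63). With the internode replicate number as a block limma called 1 gene, Potri.002G188000. Its low level in control internodes (26.7 ± 17.7) limits how far it could fall there. In the unpaired fit, the overexpression effect differed between leaf and stem for 8449 of 23372 genes. Named genes among them were Potri.005G096200 (leaf minus stem log2 7.84), Potri.002G055566 (8.46), Potri.008G099900 (8.73), Potri.012G130600 (-7.70) and Potri.019G073400 (8.29).

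Other splits of 6 libraries or plants into 3 and 3 number 10 with the real one, too few for a share under 0.05. In each of 4 comparisons 1 of 10 splits, the real one, gave as many limma calls: 1807 in young leaf against at most 1 in another split, 208 in internode against 0, 5760 in overexpression leaf against 1, and 135 for the tissue difference against 0. At an unadjusted p under 0.05 the highest other split had 4044 genes in young leaf (7197 real), 2941 in internode (5547 real), 1617 in overexpression leaf (9689 real) and 3537 for the tissue difference (4275 real). In the internode the numbers were treated as pairing the libraries, from these same data and not from the labels. There the other splits that part all 3 pairs also gave 0 limma calls, with 205 to 752 genes at an unadjusted p under 0.05.

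Overexpression effects ran in opposite directions in leaf and stem for most genes called in both. Normalization was tested by rescaling each table, and the highest share of same-direction genes under quantile and upper-quartile scaling was 33.7%, against 32.3% as deposited. Of leaf-enriched genes 15.2% fell in overexpression stems, close to the 17.2% of all genes, which decides nothing about leaf material; but their level there was a median of 1.64% (upper quartile 5.05%) of that in overexpression leaves, while the 693 genes that fell in stem and rose in leaf need a median of 53.2% leaf material (lower quartile 37.9%) and the 573 that did the reverse 26.2% (lower quartile 6.44%). Without 1 of the 4 stem libraries the correlation of leaf and stem changes ran from -0.20 to -0.15. A tissue-dependent effect of the construct may remain as a hypothesis, and a difference between transgenic lines was not tested.

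Control plant P11 lay part of the way toward the Fe-deprived plants in genes that fell, though not in genes that rose. Each control was placed between the groups (0 the other controls, 1 the Fe-deprived plants) by its own 300 genes with the smallest p in a fit without it, so the scales differ, and P11 is among the references of the other 2: over all such genes P11, P13 and P17 stood at 0.441, 0.0226 and 0.0802 in leaf and at 0.721, 0.298 and 0.493 in internode. For fallen genes P11 stood at 0.587 in leaf and 0.962 in internode, but for genes that rose at 0.0356 and 0.209, the lowest of the 3 controls in both tissues (0.0753 and 0.156 for the others in leaf, 0.305 and 0.516 in internode). RNA of Fe-deprived plants in the P11 leaf library would carry the induced transcripts, but the 29 genes that rose at least 32-fold in the fit without P11 stood there at a median of 1.77% of the Fe-deprived level. Thinning to equal depth left the fallen genes of P11 leaf at 0.590 but tests little, since that library was the deepest control leaf; in the internode, where P11 was the shallowest, they stood at 0.966 after thinning to 29840597 reads, with 0.211 and 0.397 in the other controls, and no biological explanation was tested.

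Stem-enriched genes were higher in Fe-deprived internodes. The class comes from empty-vector stems, and of its 978 genes 114 were also stem-enriched in the Fe-sufficient controls. The lowest median without any 1 library was 0.61, and thinning to 29840597 reads each left it at 0.71. Leaf material in the control internodes would have to make up 38.9% of them and lower leaf-enriched genes by a median log2 of -1.01 without Fe (upper quartile -0.49), but their median change was 0.12 (lower quartile -0.20), and -0.05 without control replicate 3. By level alone such a share is not excluded, unlike in stem. Leaf-enriched genes stood in control internodes at a median of 24.1% of control leaves (upper quartile 47.5%), so the argument rests on their change. With the 4-fold class limit the median of stem-enriched genes was 0.32. The call is lost with an estimated correlation (p = 0.0827), so a coordinated difference between these 6 plants in, for example, internode maturity remains open and may account for it; no test here separates it from Fe.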

How the results depend on the processing

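The block by internode number for the tissue difference and the alternatives for the overexpression effect between tissues, the tissue-enriched classes and the source of internode calls in the stem overlap were chosen after seeing the data. Fe deprivation in young leaf gave 1807 calls, 4744 with DESeq2 and 6530 with sample weights, and 230 to 3165 without a library. In the internode 208 calls became 97 with edgeR, 3328 with DESeq2, 1485 with sample weights, 401 with the replicate block, and 0 to 1499 without a library. Those 0 are limma counts without control replicate 2 or an Fe-deprived library, with 3205 to 5737 genes at an unadjusted p under 0.05. On simulated data 19.7% and 23.4% of DESeq2 calls in leaf and internode were false, shares that do not carry over to the real calls. Overexpression in leaf gave 5760 calls, 3151 with a 2-fold minimum, 12199 with sample weights and 2739 to 5704 without a library. Stem gave 9230, 4125 with a 2-fold minimum and 0 to 7233 without a library; the limma counts of 0, without overexpression replicate 1 or 2, had 7846 and 7408 genes at an unadjusted p under 0.05. The other alternatives moved these 4 counts by less than 1.5 times, apart from the block in young leaf given below.

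The tissue difference of the Fe response went from 135 to 72 with a pseudocount of 0.1, 24 without a filter, 270 without plant pairing, 216 with edgeR, 0 with the replicate block by leaf number (limma, 3366 genes at an unadjusted p under 0.05) and 1 with the replicate block by internode number, and was 0 to 126 without a plant (limma without P13 or P30, 3993 and 2694 at an unadjusted p under 0.05). The overexpression difference between tissues was 8449, and 5382 to 8812 without a library, lowest without overexpression stem replicate 2. Direction shares of the overlaps kept their side of 50% and of the threshold under every alternative run: 55.7% to 65.8% the same in leaf, and 17.7% to 32.1% in internode and stem. None of these alternatives left out a library, and the internode calls vanish in some fits that do. With an estimated correlation, the camera p of stem-enriched genes in the internode rose to 0.0827 (median 0.71) and that of leaf-enriched genes in overexpression leaf to 0.0714 (median -0.53); medians without a library were 0.61 to 0.83 and -0.58 to -0.48. The 4-fold class limit lowered the first to 0.32, and quantile normalization brought the second to -0.30, both still called. The 16 named genes, chosen for large changes without overlap between groups, lost their call in 34 of 248 alternatives, of which 29 left out a library.

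Replicate numbers did not pair the libraries in young leaf, overexpression leaf or stem. The block there gave 343, 6364 and 10374 calls, and 2 of 6, 4 of 6 and 4 of 4 libraries correlated best with their own number. With 2 libraries per group the deviations mirror each other, so in stem either all libraries or none could match. The stem value therefore tells nothing about pairing. Plants' leaf minus internode differences correlated at 0.124, 0.0963 and 0.277 by internode number, not all above 0.1. In the internode the block changed no call of a tissue-enriched class. The gene list alternatives were not run, because no list had members. Apart from the smaller number of libraries in the fits that leave some out, the cause of these changes was not tested. Depth was 26620695 reads or more per library, and 3 reads set the floor for genes at 0.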

Other observations

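The tests in this part on chromosomes and on strongly fallen genes, and the response groups themselves, were chosen after seeing the data. Genes that changed at least 16-fold in Fe-deprived leaves were followed through the other comparisons. Of the 75 that rose, 52 were tested in overexpression leaves, where 26 rose and 1 fell, against 12.7% rising among all genes (Fisher's exact test, p = 8.03e-11, adjusted 2.41e-10). In overexpression stems 32 were tested, 5 rose and 7 fell (rising, Fisher's exact test, p = 0.662). Of the 86 that fell, 57 were tested in overexpression leaves, where 29 rose and 14 fell (Fisher's exact tests, p = 3.73e-12 for rising and 0.000262 for falling). A gene silent in empty-vector leaves was tested only if every overexpression leaf reached the filter limit. Such genes enter the tested sets mostly through a rise. The tests of rising shares against all genes therefore cannot separate a response from this selection. In the internode of the same plants, 4 of 54 strongly induced genes rose and 0 fell, with 50 not called.

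A hypothesis was that overexpression leaves carry part of the Fe-deprivation leaf response. The share of strongly induced genes that rose there was 50%, exactly at the bound of at least 50 set before the count was seen. Strongly fallen genes rose as often, 50.9%, which is what would be seen if genes with large Fe responses rise in these leaves whatever their direction. The rising shares do not separate the 2 readings, and the filter on tested genes may have raised both shares. The falling shares differed: 1 of 52 strongly induced genes fell there (1.92%), against 14 of 57 strongly fallen genes (24.6%) and 8.61% of all genes. Starting levels in empty-vector leaves were not matched between the 2 sets, and genes low there have little room to fall. The falling shares therefore do not separate the 2 readings either. A shared Fe-deprivation response may hold for single genes such as Potri.005G096200 and Potri.002G055566, and at most in part for the strongly changed genes as a set.

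Potri.005G113400 had the highest rank by the smaller of its leaf and stem rises, log2 8.11, followed by a gene at 5.91, and took 0.354% of reads in overexpression leaves and 0.182% in stems. Whether it is the overexpressed gene was not tested, since its name is not given in the sources used here.

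Gain or loss of a whole chromosome in the overexpression plants was tested with the median log2 change of the genes carrying each of 19 chromosome numbers in their IDs. No median lay farther than 0.0994 from 0 in leaf or stem, where loss or gain of a copy would give about 0.4 or more.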
